A study of Mus musculus with 6 samples.

How the data were processed

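RNA of the cerebellum at postnatal day 0 was measured in 3 control libraries (Zeb2 f/+; hGFAP-cre) and 3 cKO libraries (Zeb2 f/f; hGFAP-cre), the groups that the labels give. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with the Illumina TruSeq RNA kit. Per the submitters' processing notes, the authors used CASAVA, TopHat and Cufflinks with genome build mm10, and the deposited values were read as FPKM, a value scaled for transcript length and library size, per locus. No label names the unit, and it was inferred from Cufflinks, its locus names and the values. Tool versions, the gene annotation, the strand setting and any scaling between libraries are not given in the sources used here. The number of a cKO library is that of its title and of its column. For cKO 1 the labels' description carries the number 3 instead. The deposit given here for cKO 1 and cKO 3 therefore rests on the titles.

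The table held 23793 loci, of which 3941 were at 0 in all 6 libraries and 333 carried more than 1 gene symbol. Of 23906 symbols, 22628 were matched directly to GENCODE M21 (GRCm38), 920 by a synonym and 358 not at all. Coordinates are those of GENCODE, since the table has none. Values were taken as log2(FPKM + 1), and loci with at least 1 FPKM in at least 3 of the 6 libraries were kept, 13612 in all.

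The read depth of the libraries is not given in the sources used here, and it limits the precision of low values. Low values moved in steps of 1 fragment, and in 7 of the 15 pairs of libraries the ratios of values under 0.1 FPKM gathered in a window of 0.06 log2 units (22.9 to 32.9% of loci), against 7.35 to 8.81% in the other 8 pairs. These pairs made 2 processing sets: control 1 with cKO 3, and controls 2 and 3 with cKO 1 and 2. Each set holds both genotypes, and neither follows the order in which the samples were deposited. Relative to control 2, depth was 1.02 for control 3, 0.797 for cKO 1 and 0.909 for cKO 2, and that of cKO 3 was 0.925 of control 1.

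Single loci were tested with limma 3.58.1 (R 4.3.3, trend on mean expression, moderated two-sided test), with Benjamini-Hochberg adjustment over all loci tested and a threshold of 0.05. Zeb2 was also tested with an exact two-sided permutation test. Log2 fold changes are cKO minus control with their SE, and group values are means ± SD of FPKM. Of 38 gene lists, written from textbook knowledge of cerebellar cell types, pathways and processes, the 35 with at least 4 measured members were tested with camera (two-sided, inter-gene correlation preset to 0.01), with adjustment over the lists. Camera with an estimated correlation and fry were run as alternatives. Members past the threshold were counted over all loci and after adjustment over the list alone. The lists, tests, threshold and rule for named genes were chosen before the data were examined.

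The rule named Zeb2, the 10 genes with the largest log2 fold change in each direction among those that passed with groups apart and a group mean of at least 2 FPKM (gene models and small RNAs passed over), up to 4 members of each list with the smallest p, and any Bergmann glia marker. Bub1, Col3a1, Olig2, Nphs1, Eif2s3x, Plxnb3, Sat1, Arg1, Hrh2, Mchr1, the Hba loci and the small RNAs were named after their values were seen.

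Alternatives chosen in advance were the replicate number as a block, the deposit as a covariate, the first deposit alone, each library left out in turn, 2 other pseudocounts, 2 other filters, 3 other scalings, sample weights (statmod 1.5.0), robust variance estimation and 2 other thresholds. Added after seeing the data were the processing set as a covariate, the second processing set alone, small-RNA loci left out (alone and with the processing set as a covariate), and X and Y loci left out. An alternative meant for read counts was not run because the table holds FPKM. On simulated data made from these libraries, 68 of 100 loci changed by 0.5 log2 units and 94 of 100 changed by 1 were called, 4.14% of 169 calls were false, and a list shifted by 0.3 was called with 0 others. Each locus was simulated independently of the others. The simulation therefore could not test camera at the preset correlation on lists whose members vary together, such as the cell cycle list (estimated correlation 0.256). Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.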

Results

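RNA was sequenced from the cerebellum of newborn mice (postnatal day 0) in 3 control and 3 conditional knockout (cKO) libraries. Zeb2 encodes a zinc finger transcription factor, and per the labels it was deleted with hGFAP-cre, a Cre recombinase driven by the human GFAP promoter, which acts in neural progenitors and glia. The control animals carried 1 floxed Zeb2 allele and the cKO animals carried only floxed alleles, both with Cre per the labels. The series asks what Zeb2 does in Bergmann glia, the radial astrocytes of the cerebellar cortex, and in the organisation of the cerebellum. The deposited table gave FPKM for 23793 loci, and 13612 of them reached 1 FPKM in at least 3 of the 6 libraries and were tested. Library sums lay between 497542 (cKO 1) and 524474 FPKM (control 1). The number of reads behind the values is not given in the sources used here, and the smallest steps between low values gave only the relative depth of libraries that shared a step pattern. Over the tested loci, log2 values correlated at Pearson r = 0.952 to 0.959 within groups and 0.942 to 0.956 between groups, across loci, which are not independent replicates. The library cKO 3 stood apart. It correlated more with control 3 (r = 0.956) and control 1 (0.953) than with cKO 1 or cKO 2 (0.952 each). On the first principal component (29.5% of the variance) it lay at 0.0643, against 0.521 and 0.535 for cKO 1 and cKO 2 and -0.483, -0.350 and -0.287 for the controls. By its title, cKO 3 shares its deposit with control 3, and by its values its processing set with control 1. These are the libraries closest to it by r. Differences in r were small, the loci include the 230 of small RNAs, and the cause was not tested. The labels name single libraries without saying that each came from a separate animal, so p-values measure the spread between these libraries.

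Zeb2 itself was measured first. Its locus (XLOC_012093, named Mir5129,Zeb2 in the table; GRCm38 chromosome 2, 44983632 to 45117395, minus strand) stood at 9.65 ± 1.73 FPKM in the controls (SD, n = 3) and at 5.30 ± 1.23 FPKM in cKO (SD, n = 3), which is 54.9% of the control mean. The control libraries gave 11.4, 9.52 and 7.995 FPKM and the cKO libraries 6.19, 3.89 and 5.81 FPKM, so every cKO value lay under every control value. The log2 fold change was -0.77 (SE 0.18). An exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 can give, and limma gave an adjusted p of 0.107, so Zeb2 did not pass the threshold of 0.05. The adjusted p was 0.0465 when loci of small RNAs were left out of the fit, a setting chosen after seeing the data, and ranged from 0.0356 to 0.312 over the alternatives tried. The labels do not say which exon is floxed, and a value for the whole locus also counts transcript outside the deleted part.

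Sex-linked genes separated the groups completely. Xist, the RNA that silences one X chromosome in female cells, was at 0.394 ± 0.105 FPKM in the controls and 144.0 ± 3.05 FPKM in cKO (SD, n = 3 each). The Y-linked genes went the other way: Eif2s3y, a translation initiation factor, was at 35.8 ± 1.36 FPKM in the controls and 0.0766 ± 0.0435 in cKO, and Ddx3y, an RNA helicase, at 16.3 ± 1.08 against 0.0178 ± 0.0102 FPKM. Kdm5d and Uty, both Y-linked histone demethylase genes, averaged 7.75 and 4.38 FPKM in the controls and at most 0.0258 FPKM in any cKO library. All 5 members of the list of sex-linked genes passed over all loci tested, with a median log2 fold change of -3.11, or -6.11 at a pseudocount of 0.1 (camera adjusted p = 9.5e-07, adjusted p = 0.0983 with an estimated correlation). The controls thus carried Y-linked transcripts and the cKO libraries Xist, and genotype and sex cannot be told apart in any comparison that follows.

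**Figure D1:**
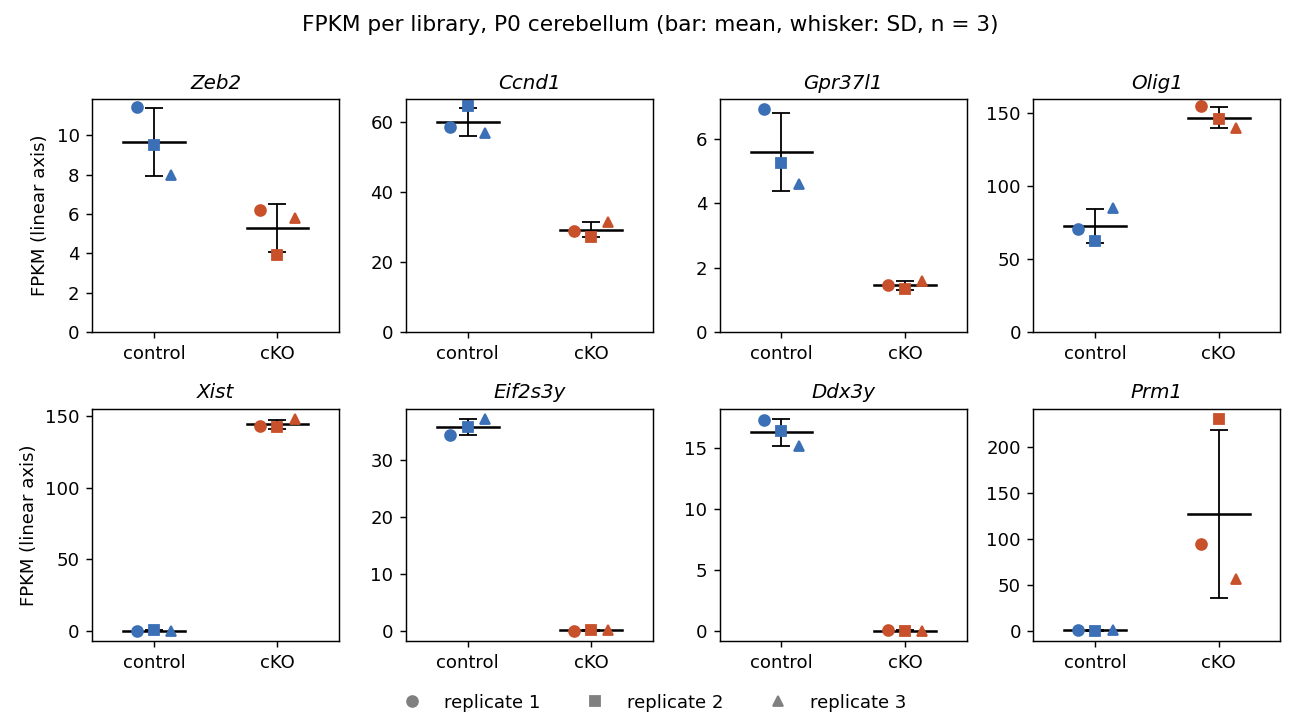
FPKM of 8 genes in each of the 6 libraries, on linear axes. Points are libraries, the horizontal bars are group means and the whiskers are SD (n = 3 per group). Zeb2 averaged 9.65 FPKM in the controls and 5.30 FPKM in cKO, Xist and Prm1 were high only in the 3 cKO libraries among the 6, and Eif2s3y and Ddx3y only in the 3 controls.

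Across all tested loci, 33 were higher and 45 lower in cKO, 78 in all at an adjusted p of at most 0.05 (limma, Benjamini-Hochberg). Among protein-coding genes outside the sex chromosomes with a group mean of at least 2 FPKM, the highest log2 fold changes of FPKM + 1 were those of Prm1, a sperm nuclear protein that replaces histones (GRCm38 chromosome 16, 10796326 to 10805839), which rose from 0.954 ± 0.411 to 127 ± 91.0 FPKM (log2 fold change 5.82, SE 0.47, adjusted p = 0.00534), and of Agr3, a gene of the protein disulfide isomerase family, which was at 0, 0 and 0.0539 FPKM in the controls and 5.02, 7.18 and 6.99 FPKM in cKO. Sod3, the extracellular superoxide dismutase, rose from 2.79 ± 1.39 to 11.3 ± 1.21 FPKM, and Ackr4, an atypical chemokine receptor, from 0.148 ± 0.0402 to 2.47 ± 0.603 FPKM. Gbx2, a homeobox gene of the anterior hindbrain, rose from 7.75 ± 1.27 to 17.6 ± 1.74 FPKM (log2 fold change 1.10, SE 0.12). Olig1, a transcription factor of the oligodendrocyte lineage, rose 2.02-fold from 72.6 ± 11.5 to 146.9 ± 7.40 FPKM, and Kank4, Sntb1 and Pmaip1 rose by log2 fold changes of 1.30, 1.07 and 0.96.

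Among the autosomal genes that fell, Mfap4, a microfibril-associated protein, went from 69.9 ± 13.1 to 18.5 ± 5.31 FPKM (log2 fold change -1.88, SE 0.21, adjusted p = 0.0235). Ccnd1, cyclin D1 (GRCm38 chromosome 7, 144929931 to 144939925), went from 59.9 ± 4.03 to 29.2 ± 2.20 FPKM (log2 fold change -1.01, SE 0.07, adjusted p = 0.00305). Gpr37l1, a receptor of Bergmann glia and astrocytes (GRCm38 chromosome 1, 135160234 to 135167681), went from 5.59 ± 1.21 to 1.45 ± 0.136 FPKM. Prdm13, a transcriptional regulator of GABAergic progenitors, fell by 1.31 on the log2 scale, Kirrel2, a cell adhesion gene, by 1.20, and Ass1, argininosuccinate synthase, by 1.14. Of the 78 called loci, 8 are loci of small RNAs, 4 lie on X and 4 on Y, and 62 are neither. All 78 had every cKO value on one side of every control value, as did 23.9% of the tested loci, against 10% by chance.

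The number of calls depended strongly on single libraries and on the small-RNA loci. It was 33 without control 1, 28 without control 2, 55 without control 3, 21 without cKO 1, 27 without cKO 2 and 44 without cKO 3, while leaving out the 230 small-RNA loci raised it to 325 (128 higher and 197 lower). Unless stated, passing over all loci refers to the main fit, with the small-RNA loci included. Some genes given below as not passing over all loci did pass with those loci left out, a setting chosen after seeing the data. Ccnd1, Prm1, Agr3, Ackr4 and the 5 sex-linked genes stayed called with any 1 of the 6 libraries left out, and the other protein-coding genes described here as changed lost their call in 1 or more of those 6 fits, the alpha globin locus aside, which was not followed across them.

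The list of Bergmann glia markers did not move as a whole in either direction, which leaves open changes of single members. Its 23 members had a median log2 fold change of -0.06, with 9 above and 14 below 0 (camera adjusted p = 0.492). That median was -0.021 without control 1, -0.031 without control 3, -0.0052 without cKO 2, -0.028 without cKO 3 and -0.0046 in the first deposit only. Gpr37l1 fell and Slc4a4, a sodium bicarbonate cotransporter, rose from 19.8 ± 1.81 to 32.4 ± 2.79 FPKM (log2 fold change 0.68, SE 0.09, adjusted p = 0.0336), and the remaining 21 did not pass over all loci. Adjusted over the list alone, 3 were higher (Slc4a4, Fgfr3 and Etv4) and 5 lower (Gpr37l1, Aqp4, Gria1, Etv5 and Wif1). With small-RNA loci left out, 2 of the 23 were higher and 2 lower over all loci. Before adjustment, 10 of the 23 had a limma p under 0.05 in the main fit, as had 2396 of the 13612 tested loci. Gdf10, a growth factor of the BMP family that marks Bergmann glia, was at 115 ± 13.2 FPKM in the controls and 54.7 ± 30.3 FPKM in cKO (log2 fold change -1.26, SE 0.47), and Slc1a3, the glutamate transporter GLAST, at 269 ± 29.7 and 160 ± 59.6 FPKM. Neither passed (adjusted p = 0.241 and 0.221), although every cKO value lay under every control value. Fabp7, a fatty acid binding protein of radial glia, differed by a log2 fold change of 0.0032 (SE 0.09), with a sign that depended on the scaling and on the libraries included.

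**Figure D2:**
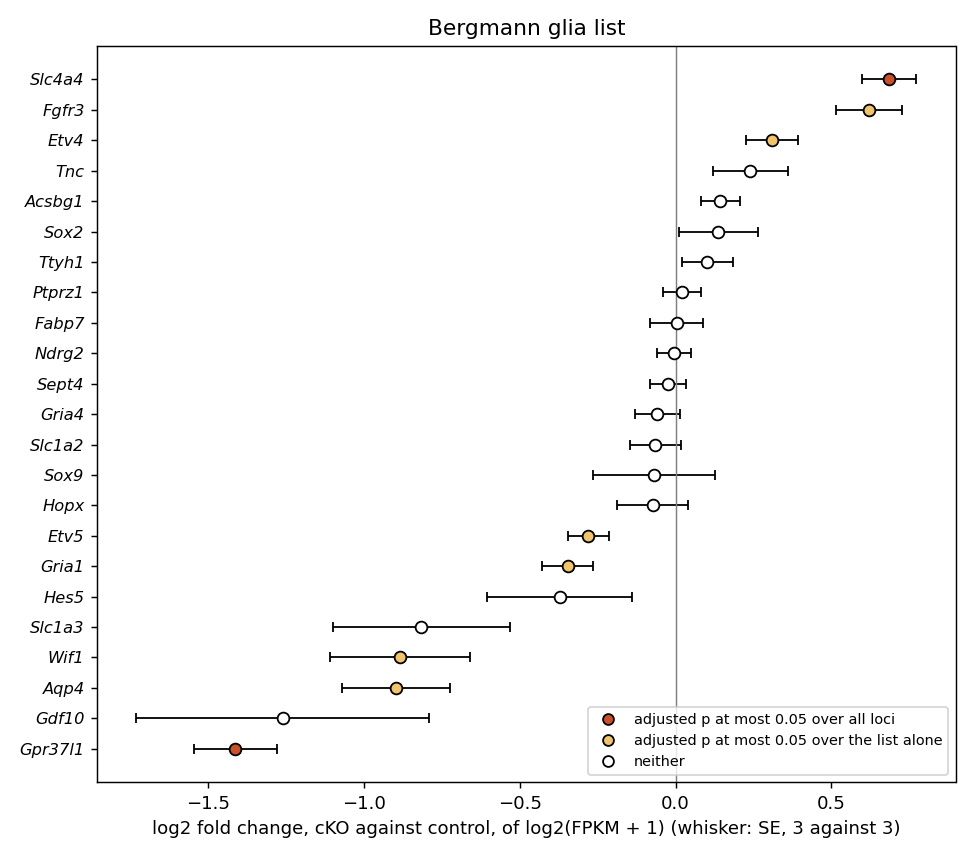
Log2 fold change of log2(FPKM + 1), cKO against control, for the 23 measured Bergmann glia markers. Points are estimates from 3 libraries against 3 and whiskers are SE. Red points passed over all loci tested, yellow points passed when adjusted over the list alone, and members lie on both sides of 0, from -1.41 for Gpr37l1 to 0.68 for Slc4a4.

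Other lists of glial and progenitor genes also held members that moved in opposite directions. Of 19 maturing astrocyte genes, S100b, a calcium-binding protein, fell from 4.43 ± 0.353 to 2.13 ± 0.266 FPKM and passed, while Aldoc and Gja1 had log2 fold changes of 0.68 and 0.52 and in the main fit passed only when adjusted over the list alone (3 higher and 2 lower). With small-RNA loci left out, Aldoc and Gja1 passed over all loci (limma adjusted p = 0.0254 and 0.0275). Of 18 ventricular zone progenitor genes, Prom1 rose from 4.97 ± 0.258 to 7.53 ± 0.590 FPKM, while Vim, the intermediate filament gene vimentin, was at 556 ± 21.01 and 334 ± 51.2 FPKM (log2 fold change -0.74, adjusted p = 0.0644), and Ptf1a, a transcription factor of neural progenitors, had a log2 fold change of -0.88 without passing over all loci. Adjusted over the list alone, 1 of the 18 was higher and 2 were lower. Of 11 oligodendrocyte precursor genes, Olig1 rose, Olig2 had a log2 fold change of 0.65, and Gjc3, Gpr17 and Pdgfra had log2 fold changes of -0.79, -0.88 and -0.29. Adjusted over the list alone, 2 of the 11 were higher and 3 lower. None of these 3 lists moved as a whole (camera adjusted p = 0.774, 0.177 and 0.309).

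Genes of the cell cycle were lower in cKO. All 24 had negative log2 fold changes, with a median of -0.41 (camera adjusted p = 1.3e-19, adjusted p = 0.141 with an estimated correlation). Over all loci 5 passed: Aurkb, a mitotic kinase (19.2 ± 0.796 to 13.4 ± 0.594 FPKM), Mcm4, a subunit of the replicative helicase (22.4 ± 0.973 to 16.5 ± 0.224 FPKM), Cdc20, Top2a and Bub1. Adjusted over the list alone, 23 passed. With 1 library left out, Aurkb, Mcm4, Top2a and Bub1 lost the call over all loci in each of the 6 fits, and Cdc20 in 5 of 6. With small-RNA loci left out, 16 of the 24 passed over all loci, all of them lower. The median lay between -0.40 and -0.39 under 3 other scalings of the libraries.

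Granule neuron progenitor genes and Sonic hedgehog pathway genes, which share members, were lower too. Of 17 granule neuron progenitor genes, Ccnd1 and Mfap4 fell over all loci and 7 fell when adjusted over the list alone, with a list median of -0.28 (camera adjusted p = 8.8e-06, adjusted p = 0.304 with an estimated correlation). Gli1 and Gli2, transcription factors of the hedgehog pathway, were at 21.03 ± 2.45 and 9.52 ± 0.971 FPKM in the controls and 12.5 ± 1.87 and 6.00 ± 0.535 FPKM in cKO, and in the main fit passed only within the list. With small-RNA loci left out, Gli1 and Gli2 passed over all loci (limma adjusted p = 0.0255 and 0.0206). Of 14 Sonic hedgehog pathway genes, 1 fell over all loci and 5 when adjusted over the list alone (median -0.17, or -0.088 without cKO 2, camera adjusted p = 0.00493, adjusted p = 0.392 with an estimated correlation). Differentiating granule neuron genes did not move as a whole (17 measured, median 0.03, camera adjusted p = 0.544), with 1 higher and 1 lower over the list alone.

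Cytosolic ribosomal protein genes all had negative log2 fold changes, 45 of 45, with a median of -0.16, or -0.098 without cKO 1 and -0.092 with quantile normalization (camera adjusted p = 9.3e-08, adjusted p = 0.528 with an estimated correlation), and none passed over all loci or over the list alone (limma), while 7 had a limma p under 0.05 before adjustment. Rpl28 was at 883 ± 15.3 and 753 ± 53.4 FPKM, and Rpl23 at 381 ± 18.5 and 336 ± 10.4 FPKM. Myelinating oligodendrocyte genes were lower as a list (10 measured, median -0.10, camera adjusted p = 0.025, adjusted p = 0.392 with an estimated correlation). None of the 10 passed over all loci by limma, and the 4 with a p under 0.05 before adjustment were lower over the list alone, among them Bcas1, Mbp and Cnp, with log2 fold changes of -0.45, -0.34 and -0.32. That list's call was lost without control 1 (adjusted p = 0.0753), without cKO 2 (0.0882), with X and Y loci left out (0.0818), in the first deposit only (0.0633) and in the second processing set only (0.0679). Its median was -0.053 without a filter and -0.32 at a mean of at least 5.

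**Figure D3:**
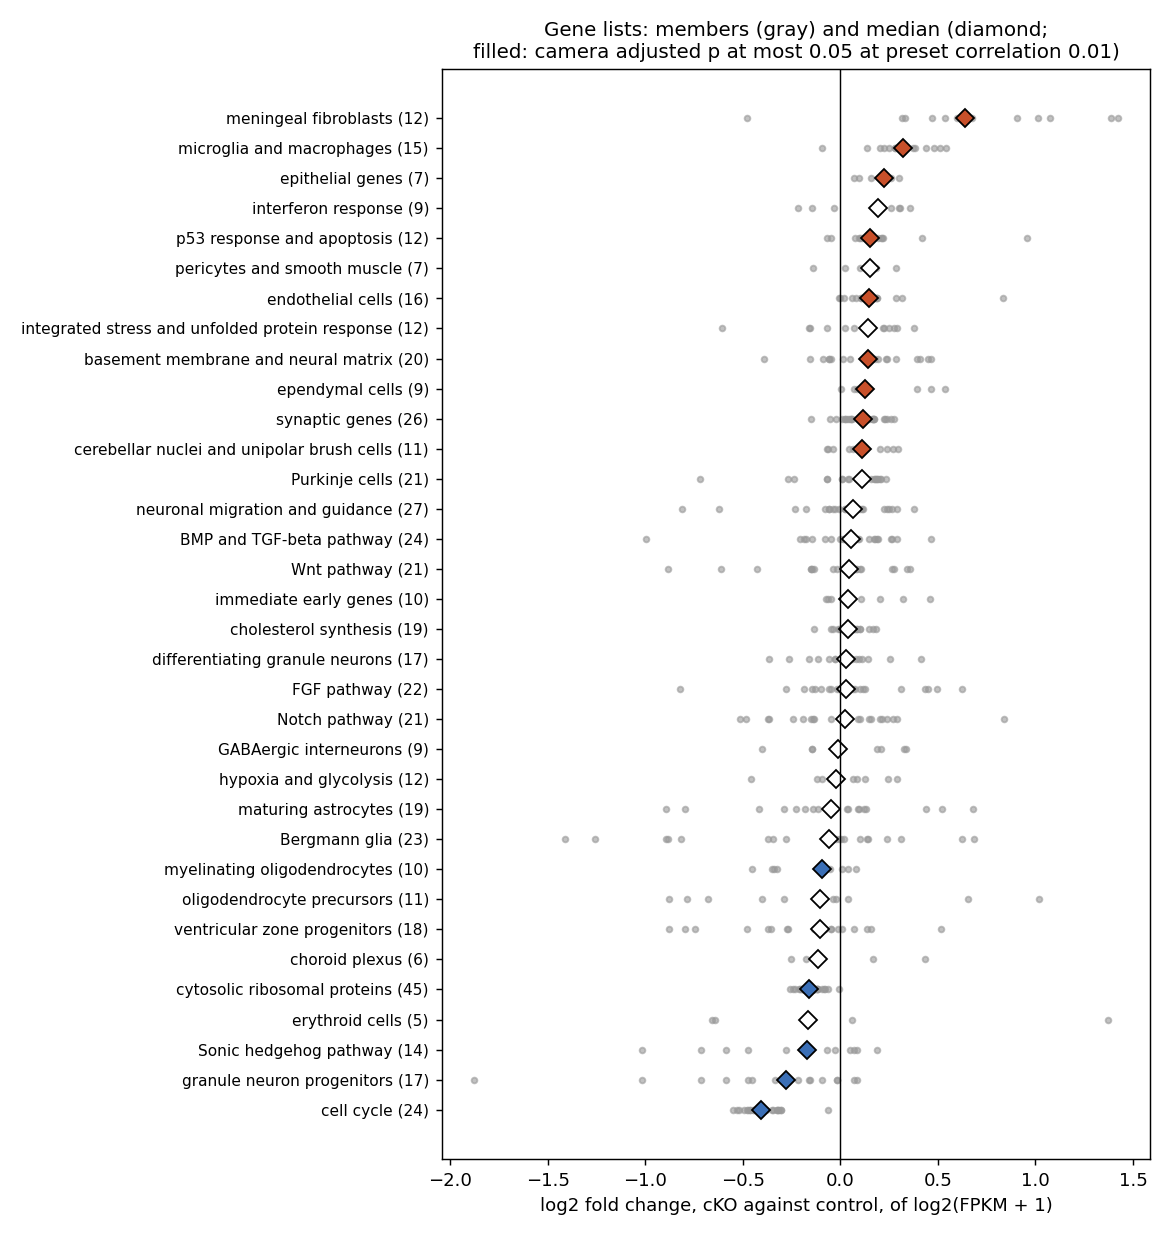
Log2 fold change of log2(FPKM + 1), cKO against control, for 34 gene lists, the sex-linked list left out. Gray points are member genes, diamonds are list medians, filled where camera passed at the preset correlation of 0.01, and the number of measured members stands in parentheses. The lowest median is that of the cell cycle list (-0.41) and the highest that of the meningeal fibroblast list (0.64), and none of the filled lists passed with an estimated correlation.

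Several lists of non-neuronal cell types were higher in cKO. Of 15 microglia and macrophage genes, 14 had positive log2 fold changes (median 0.32, camera adjusted p = 5.5e-09, adjusted p = 0.0983 with an estimated correlation). Csf1r, the receptor that microglia need to survive, rose from 4.10 ± 0.0642 to 6.13 ± 0.490 FPKM (adjusted p = 0.0483). Adjusted over the list alone 11 were higher, among them the complement genes C1qa, C1qb and C1qc (log2 fold changes 0.51, 0.44 and 0.37). Meningeal fibroblast genes had a median of 0.64 over 12 members, 0.41 without cKO 2, 0.97 at a pseudocount of 0.1 and 1.14 in the second processing set only (camera adjusted p = 9.1e-04, adjusted p = 0.528 with an estimated correlation). None passed over all loci by limma (4 had a p under 0.05 before adjustment), while over the list alone Ptgds and Foxc1 were higher (log2 fold changes 1.01 and 0.33) and Islr lower (-0.48), and the collagen gene Col3a1 was at 4.07 ± 4.52 and 12.2 ± 9.97 FPKM, a spread larger than the control mean. Endothelial genes (16 measured, median 0.14, or 0.058 without control 2, camera adjusted p = 0.00173, adjusted p = 0.528 with an estimated correlation) and ependymal genes (9 measured, median 0.13, camera adjusted p = 0.025, adjusted p = 0.528 with an estimated correlation) each had 1 member higher over the list alone, Mfsd2a and Mia. The ependymal call was lost without control 1 (adjusted p = 0.0739), cKO 1 (0.176) or cKO 3 (0.0854). Its median was 0.047 without cKO 1, 0.32 without cKO 2 and 0.073 without cKO 3. The ependymal call was also lost in the first deposit only (adjusted p = 0.113, median 0.070), in the second processing set only (0.186, median 0.065), with sample weights (0.0814, median 0.068), at a mean of at least 5 (0.0676, median 0.26) and without a filter (0.0514). Pericyte and smooth muscle, choroid plexus and erythroid lists did not move as a whole (medians 0.15, -0.12 and -0.17, camera adjusted p = 0.206, 0.806 and 0.631). In the erythroid list 1 of the 2 loci named Hba-a1,Hba-a2, genes of alpha globin, was listed at 0 in all controls and at 2.14, 1.15 and 1.56 FPKM in cKO and passed. The other locus of that name went the other way without passing, at 7.05 ± 4.02 FPKM in the controls and 3.77 ± 1.32 FPKM in cKO (log2 fold change -0.64).

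Synaptic genes and p53 response genes were higher as lists. Of 26 synaptic genes 23 had positive log2 fold changes (median 0.11, camera adjusted p = 2.4e-04, adjusted p = 0.119 with an estimated correlation). None passed over all loci by limma (9 had a p under 0.05 before adjustment), and 3 were higher over the list alone, among them Nlgn1 and Cplx2 (log2 fold changes 0.26 and 0.27). Of 12 p53 response and apoptosis genes (median 0.15, camera adjusted p = 6.4e-04, adjusted p = 0.392 with an estimated correlation), Pmaip1, a pro-apoptotic gene also known as Noxa, rose from 3.10 ± 0.294 to 7.02 ± 1.27 FPKM, and Cdkn1a, the cyclin-dependent kinase inhibitor p21, from 47.5 ± 2.43 to 63.7 ± 2.52 FPKM. These 2 were also the members higher over the list alone.

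Upward shifts were also seen in 3 further lists. Epithelial genes, of which 7 of 28 were measured, had a median of 0.22, or 0.13 without control 2 and 0.098 without a filter (camera adjusted p = 0.00582, adjusted p = 0.392 with an estimated correlation), with Spint2 alone higher over the list. Basement membrane and neural matrix genes had a median of 0.14 over 20 members (camera adjusted p = 0.0239, adjusted p = 0.598 with an estimated correlation). Within that list the proteoglycan genes Ncan and Bcan had log2 fold changes of 0.45 and 0.47 and Vcan of -0.39, and 3 were higher and 1 lower over the list alone. Cerebellar nuclei and unipolar brush cell genes had a median of 0.11 over 11 members, none of which passed over the list by limma although 4 had a p under 0.05 before adjustment (camera adjusted p = 0.0407, adjusted p = 0.392 with an estimated correlation). The matrix call was lost without cKO 1 (adjusted p = 0.323, median 0.091) or cKO 2 (0.109, median 0.068). Its median was 0.28 without cKO 3, 0.30 in the first deposit only and 0.29 in the second processing set only. The call for cerebellar nuclei genes was lost without control 1 (0.0753), control 3 (0.0706) or cKO 3 (0.280). Its median was 0.17 without control 2 and 0.073 without cKO 2. The call for cerebellar nuclei genes was also lost in the second processing set only (0.386), in the first deposit only (0.298, median 0.072), with quantile normalization (0.0539), median-ratio scaling (0.0509), sample weights (0.0534), the processing set as a covariate (0.0664, or 0.0629 with small-RNA loci left out as well), no filter (0.0717) and a mean of at least 5 (0.111, median 0.065).

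Of the neuronal and signalling lists that did not move as a whole, the Purkinje cell and FGF pathway lists held single genes that passed over all loci, and the GABAergic interneuron and Notch pathway lists held none. Pvalb, the calcium buffer parvalbumin, fell from 4.61 ± 0.474 to 2.40 ± 0.247 FPKM in the Purkinje cell list (21 measured, median 0.11, camera adjusted p = 0.0683), where Lhx5 was also lower over the list alone. In the FGF pathway list (22 measured, camera adjusted p = 0.356), Fgfr4 fell from 3.91 ± 0.273 to 1.79 ± 0.404 FPKM and Spry1, a feedback inhibitor of FGF signalling, rose from 12.1 ± 0.879 to 16.7 ± 0.187 FPKM, and 4 were higher and 3 lower over the list alone. In the GABAergic interneuron list (9 measured, camera adjusted p = 0.473) Kit had a log2 fold change of -0.40, with 3 higher and 1 lower over the list alone. Hey2 and Hey1 of the Notch pathway list (21 measured, camera adjusted p = 0.544) had log2 fold changes of 0.84 and -0.37, with 3 higher and 3 lower over the list alone.

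Camera tests a net shift in 1 direction, and by it the remaining tested lists did not move as a whole. Camera gave adjusted p = 0.0833 for cholesterol synthesis, 0.182 for neuronal migration and guidance, 0.216 for immediate early genes, 0.228 for the interferon response, 0.244 for the BMP and TGF-beta pathway, 0.279 for the integrated stress and unfolded protein response, 0.662 for the Wnt pathway and 0.883 for hypoxia and glycolysis. No member of these 8 lists passed over all loci, and over the list alone 3 Wnt pathway genes and 1 stress response gene were lower. A mixed fry test takes changes in either direction. Its p before adjustment ran from 1.3e-04 (stress response and hypoxia lists) to 0.208 (immediate early genes) over these 8 lists. That test does not compare a list with other genes, and 2396 of the 13612 tested loci had a limma p under 0.05. Median, mean and camera direction differed in sign for the erythroid, GABAergic interneuron, Notch, Wnt and hypoxia lists. In total 15 of 35 tested lists moved, 9 upward and 6 downward, at the preset correlation of 0.01, and 0 with an estimated correlation, at which the camera p before adjustment was under 0.05 for the same 5 lists that fry called. By fry, which does not compare a list with other genes, those 5 passed: cell cycle, microglia and macrophages, sex-linked, granule neuron progenitor and synaptic genes. The lists of brainstem and midbrain neurons and of replication-dependent histones had 3 measured members each and the list of mitochondrially encoded genes had 0, so these 3 of the 38 lists were not tested.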

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

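The settings on processing sets, on small-RNA loci and on X and Y loci were chosen after seeing the data. The count of 78 changed loci was 15 with the replicate block, 22 with the deposit as a covariate, 28 without a filter, 30 at a mean of at least 5, 336 with robust variance estimation (all 78 among them), 29 with a log2 fold change of at least 1, 409 at an adjusted p of at most 0.1 and 30 in the second processing set only. It was 325 with small-RNA loci left out and 506 with the processing set as a covariate as well, each holding all 70 of the other calls. With 1 library left out it ranged from 21 to 55. It was 52 to 87 under the first deposit only, 2 pseudocounts, 3 scalings, sample weights, the processing set as a covariate, and X and Y left out. The same numbers in both groups do not pair the libraries: deviations from the group mean correlated at -0.027, 0.037 and 0.049 between libraries of equal number. Small-RNA loci had a median residual SD of 1.34 against 0.0943 for other loci, and the prior degrees of freedom were 2.80 with them and 4.86 without. For the other changed counts the cause was not tested, beyond fewer libraries or loci.

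Zeb2 was lower under each alternative, and passed only with small-RNA loci left out (log2 fold change -0.77, adjusted p = 0.0465) and with the processing set as a covariate as well (-0.77, adjusted p = 0.0356). The list count of 15 was 0 with an estimated correlation, 5 by fry and 11 to 17 otherwise. The median of the Bergmann glia list stayed below 0, at -0.024 with camera turned upward at a mean of at least 5 (adjusted p = 0.868). Fabp7 turned negative in the first deposit only (-0.00038), with quantile normalization (-0.0073), sample weights (-0.0028) and the second processing set only (-0.028), and ranged from -0.021 to 0.024 with 1 library left out. The meningeal fibroblast call was lost at a mean of at least 5 (adjusted p = 0.405). Of 48 called loci among 98 named, 17 were called with any 1 library left out and 31 lost the call at least once. Those 17 were the 8 called small-RNA loci, the 5 sex-linked genes, and Ccnd1, Prm1, Agr3 and Ackr4. The unknown read depth limits loci near 1 FPKM.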

Other observations

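The tests on sex and on dilution by other cell types were chosen only after the result was seen, as was leaving out small-RNA loci.

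The list of brainstem and midbrain genes had 3 measured members, was not tested and held none that passed over all loci by limma in the main fit. Dbh, the enzyme that makes noradrenaline, was at 1.92, 4.45 and 6.78 FPKM in the controls and 0.326, 0.536 and 0.823 FPKM in cKO (log2 fold change -1.69, limma adjusted p = 0.0839), and Slc6a2, the noradrenaline transporter, at 3.55 ± 1.73 and 0.501 ± 0.285 FPKM (-1.54, adjusted p = 0.0762). Both passed when adjusted over those 3 genes alone, and Th, tyrosine hydroxylase, did not (-0.72, limma adjusted p = 0.303 over all loci). With small-RNA loci left out, Dbh and Slc6a2 passed over all loci (limma adjusted p = 0.0304 and 0.0275). Nphs1, the gene of nephrin, fell from 3.90 ± 0.349 to 1.77 ± 0.309 FPKM, and Kirrel2, a nephrin-like adhesion gene, fell as well. Kirrel2 (30447534 to 30457690) and Nphs1 (30458315 to 30487223) are neighbours on GRCm38 chromosome 7, so their changes may not be independent. Arg1, arginase 1, rose from 1.89 ± 0.218 to 4.36 ± 0.289 FPKM, and Mchr1 and Hrh2, receptors for melanin-concentrating hormone and histamine, rose by log2 fold changes of 0.79 and 0.58.

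Loci of small RNAs made up 8 of the 78 calls. In the controls, Snord65 was at 589, 675 and 664 FPKM, Snord49a at 609.6, 297 and 292, Snord49b at 224, 260.2 and 256, Snord1b at 125, 204 and 67.0, Scarna10 at 93.5, 221 and 109, Mir7058 at 83.1, 79.2 and 77.9 and Mir7033 at 85.4, 51.6 and 50.7, and each was listed at 0 in all 3 cKO libraries. Mir135a-1 was listed at 0 in the controls and at 75.8, 33.3 and 36.4 FPKM in cKO. Snord49b, Snord49a and Snord65 lie side by side on chromosome 11 (GRCm38, 62603079 to 62604586), so they are not separate observations. Small-RNA loci varied widely between libraries, with a median residual SD of 1.34 against 0.0943 for other loci. Whether these zeros reflect absent transcripts was not tested.

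The groups were separated by Xist and by Y-linked genes. Sex-chromosome genes were not the whole of the calls, since 10.3% of the 78 called loci lay on X or Y against 3.50% of the tested loci. An exchange of the control and cKO labels is argued against by the Zeb2 log2 fold change of -0.77 (SE 0.18), with every cKO value under every control value. This evidence is limited, since Zeb2 did not pass in the main fit (limma adjusted p = 0.107, exact permutation p = 0.1). Sex of the animals may be a cause of autosomal changes and cannot be told apart from genotype, because 0 cKO libraries were among those with Xist under 1 FPKM. On the X chromosome outside Xist, Eif2s3x and Sat1 were higher (log2 fold changes 0.50 and 0.72) and Plxnb3 was lower (-0.80).

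Prm1 stood at 94.9, 229.9 and 56.6 FPKM in the cKO libraries and at 1.33, 0.516 and 1.01 FPKM in the controls. Germ cell RNA is argued against, since Prm2, Tnp1 and Tnp2 together reached 0.192% of Prm1 in cKO, and transcription through the native region by a median log2 fold change of 0.018 over its 3 measured neighbours, Clec16a, Rmi2 and Socs1. Some Cre transgenes carry Prm1 sequence at their end, and such a transcript may be the source: 3 of 3 cKO libraries lay above every control, but the table holds no reads to place on the gene, so this stays open. The labels give Cre to both groups, and the table does not show whether the controls carried the same transgene or transcribed it less. If the controls did not carry it, its presence would be confounded with genotype in each comparison here, that of Zeb2 included.

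Genes of the cell cycle were lower in cKO by a median of -0.41. A trend with transcript length or GC content as the whole cause is argued against by a median of -0.39 after such trends were removed, and scaling between libraries by a highest median of -0.39 over 3 other scalings. A smaller share of all neural cells as the whole cause is argued against by the 84 measured genes of 5 neuronal lists, whose median was 0.082 (61 above 0), and 0.079 with an SE of 0.0095 between libraries when taken per library. The synaptic and cerebellar nuclei lists, both higher at the preset correlation, are among these 5, so the outcome was not independent of those results. An earlier comparison of meningeal fibroblast with choroid plexus genes did not decide on a smaller share of neural cells (0.65 per library, SE 0.40). A smaller share of dividing progenitors, or less division in them, may account for the lower values, as a hypothesis that these libraries could not test and that counts of dividing cells in tissue sections would decide, and sex remains confounded with genotype here too.

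For ribosomal protein genes (median -0.16), 142 abundant genes of the same transcript length range (348 to 3706 bp) had a median of -0.0011. Only the limits of that range were matched, not the typical length, so this comparison cannot decide whether short transcripts are the cause. After trends with length and GC content were removed, the ribosomal median was -0.13 (camera adjusted p = 1.2e-07 at the preset correlation). This argues against such a general trend as the whole cause. In the main fit the list did not pass with an estimated correlation (camera adjusted p = 0.528). Within 20 Mb of Zeb2, 2 of 261 tested loci were called against 76 of 13350 elsewhere (one-sided Fisher's exact p = 0.443). Of the 10 splits of the 6 libraries into groups of 3, 1 gave as many calls as the real one, which is the real split itself (78, highest other 10), and 10 splits are too few for a share under 0.05.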
